A study of Homo sapiens with 90 samples.

How the data were processed

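RNA was sequenced from 6 established human cancer cell lines, A375, A549, H3122, N87, PC9 and RT112, in 5 arms of 3 libraries each, 90 libraries in 30 groups. Per the submitters' processing notes, RNA was purified with an RNeasy micro kit and libraries were made with a NEBNext Ultra RNA kit. The deposited values are expected counts per gene, which the authors obtained with RSEM 1.2.12 over Bowtie2 2.2.1 alignments to hg19. The gene annotation they used is not given in the sources used here. Between 7.83 and 13.75% of the values of a library are not whole numbers, because reads are shared between genes in proportion. The table holds 53893 gene IDs. Of these, 47111 were matched to a symbol and 6782 were not, and the latter hold 1.26% of all counts. For 876 IDs that share a symbol with a more abundant ID, the ID stands in place of the symbol. Some IDs without a symbol met the rule for named genes and are not printed. GENCODE v29 was used for symbols, for the names of genes on the Y chromosome and for transcript lengths, and no coordinate was taken from it.

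Library totals ran from 5.64 to 14.36 M expected counts with a median of 11 M. They were 5.64 to 12.96 M in A375, 6.20 to 12.94 in A549, 8.79 to 13.53 in H3122, 6.47 to 12.41 in N87, 9.79 to 14.36 in PC9 and 11.92 to 13.96 in RT112. Values were rounded to whole numbers before testing. Groups came from the sample titles, with the drug, dose and time given there. One A375 library of the vemurafenib arm carries another tissue label than the rest of its line, and its nearest library is of its own line and group. All libraries were kept.

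The cell line was the replicate for tests across lines. Counts of the 3 libraries of a line and arm were summed, and the 30 sums were fitted in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with TMM scaling and a term for each line. The 11877 genes at 1 CPM or more in at least 3 libraries of every line were tested. Within each line the 15 libraries were fitted together in edgeR after filterByExpr, which kept 14810 to 16106 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 CPM values carry a prior count of 2, and log2 fold changes are those of the edgeR fits at the default prior count of edgeR. The comparisons were the targeted drug at 48 h against DMSO, THZ1 against DMSO, the combination against the targeted drug at 48 h, and the targeted drug at 7 days against DMSO. The combination against DMSO, 7 days against 48 h and the interaction of both drugs were tested across lines as well.

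Replicate numbers in the titles recur between arms, but of 24 comparisons only 7 have 3 shared numbers. Correlations of deviations between libraries with the same number ran from -0.12 to 0.10 outside RT112 and from 0.01 to 0.29 in RT112, and in none of the 7 was every one above 0.1. None of the 7 was in RT112, so this rule could not decide there, and RT112 replicate 1 gave 0.29, 0.12 and 0.15. Libraries were not paired in any line, and a replicate block was tried as an alternative. RT112 replicate 1 in 4 arms and H3122 replicate 1 at 7 days stood apart from their groups and were left out in a setting added later. The lowest correlation between libraries of a group was 0.9903.

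Gene lists were fixed before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. The 27 lists cover MAPK pathway output and feedback, proliferation, receptor tyrosine kinases, FOXO targets, interferon response, antigen presentation, inflammatory cytokines and NF-kB feedback, mesenchymal genes, YAP and TEAD targets, and immediate-early and short-lived transcripts. They also cover homologous recombination and replication stress, the transcription kinases and elongation machinery, p53 targets, the BCL2 family, lysosome and autophagy, cholesterol synthesis, glycolysis, the integrated stress response, drug-tolerant state genes, ribosomal proteins and mitochondrial genome transcripts. The last 6 hold markers of melanocytes, lung, gastric and urothelial epithelium, blood cells, and fibroblasts and endothelium. Of the listed genes 4 (TXNIP, SOD2, CCL5 and PECAM1) were not found in the table, and 4 genes are in more than 1 list. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison, which left 21 across lines. Each was tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance.

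Genes raised by the targeted drug were those called and at least 2-fold higher at 48 h in a line. Their share called lower in the combination than under the targeted drug was set beside that of other tested genes matched in 20 bins of expression. It was also set beside 5 simulations per line in which combination effects were shuffled among genes within bins, since both comparisons use the same targeted-drug libraries. THZ1 alone was simulated likewise, with THZ1 effects shuffled. The mean of the 6 line differences was tested with an exact two-sided sign-flip test of 64 patterns. Changes of 12036 genes tested in all 6 lines were correlated between the 15 pairs of lines.

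The rule for named genes took, per main comparison, the 8 largest rises and 8 largest falls among called genes that moved the same way in all 6 lines. It took up to 4 called members of each list, or the 2 largest changes of a list without calls. Within each line it took the 3 largest rises and falls among called genes with a mean log2 CPM of at least 1, and the 3 largest falls in the combination among raised genes. It always took the 10 target genes BRAF, MAP2K1, MAP2K2, ALK, EGFR, ERBB2, FGFR3, CDK7, CDK12 and CDK13. The text prints part of these, in order of size. One gene that the rule names is not reported here. Levels are TMM-scaled CPM with the SD of 3 libraries. Symbols that start with MIR, SNOR, LOC, LINC, RNU or RNY or hold -AS, XIST and Y-linked genes were left out of the parts that rank genes, and other non-coding genes were not. The levels of SPRY4 in H3122, of NKX2-1 and of the blood cell markers, and the plotted genes, were picked after their values were seen.

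Alternatives for tests across lines were RLE scaling, library size alone, filterByExpr over the 30 groups (19655 genes), at least 10 CPM in every line (8139 genes), DESeq2 1.42.0 on the sums, limma 3.58.1 on mean log2 CPM, only the arms compared, no term for the line, and each line left out. Within lines they were RLE scaling, library size alone, no filter, a 10 CPM minimum, DESeq2, a replicate block, only the 2 arms compared, each library left out and a 2-fold minimum. The methods were tested on simulated data with 200 changed genes. Across lines edgeR recovered 73% of 2-fold and 95% of 4-fold changes with 11 false calls among 179, and DESeq2 made 32 false calls there. One draw was simulated per fit, and another draw gives other values. Within lines edgeR recovered 70 to 82% of 2-fold and 85 to 97% of 4-fold changes, with 6 to 13 false calls.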

Results

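RNA sequencing was done on 6 human cancer cell lines, each treated with a kinase inhibitor chosen for its driver. A375 melanoma cells received the BRAF inhibitor vemurafenib at 1 uM. A549 lung cells received the MEK inhibitor GSK1120212 (trametinib) at 200 nM. H3122 lung cells received crizotinib, an ALK inhibitor, at 250 nM. N87 gastric cells received lapatinib, an inhibitor of EGFR and ERBB2, at 100 nM. PC9 lung cells received the EGFR inhibitor erlotinib at 1 uM, and RT112 bladder cells the FGFR inhibitor BGJ398 at 1 uM. THZ1, a covalent inhibitor of the transcription kinase CDK7 that also acts on CDK12 and CDK13, was given at 25 nM to N87, 50 nM to A375 and H3122, 100 nM to PC9 and RT112, and 150 nM to A549.

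Each line had 5 arms of 3 libraries, 90 libraries in all. The arms were 0.1% DMSO, the targeted drug, THZ1 and the combination, each for 48 h, and the targeted drug for 7 days. Totals ran from 5.64 to 14.36 M expected counts per library (median 11), and the arm means from 10.6 to 11.1 M. All 90 libraries correlated best with another library of their own line and arm. The 7-day arm has no 7-day vehicle control, so it was compared with DMSO at 48 h, and drug and time cannot be told apart in it. The labels do not say whether the 3 libraries of an arm come from separate cultures, so p-values within a line measure spread between libraries that may be technical replicates. No spike-in was added, and a decrease of all RNA would not be visible.

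The first comparison asked what each targeted drug did within 48 h. The transcriptional output of the MAPK pathway and the genes of DNA replication and mitosis were lower. Genes that FOXO factors switch on, lysosomal genes, and interferon and antigen presentation genes were higher as groups. Camera called 11 of 21 lists, and 0 with an estimated correlation (adjusted p = 0.299 to 0.399 for the lists named here). Among the largest rises were SELENOP (selenoprotein P), the PI3K inhibitor protein PIK3IP1 and the pro-apoptotic BMF. The largest falls were in the ETS factors ETV4 and ETV5 and the feedback inhibitor SPRY4. Across lines, 4372 of 11877 genes were called, 2186 up and 2186 down, and 2988 of them had the same direction in all 6 lines.

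Of the rises that held in 6 of 6 lines, SELENOP had 3.40 ± 0.57 on the log2 scale (adjusted p = 0.000228). The ± of a log2 change across lines is the SE of the fit, whose spread comes from all arms. PIK3IP1 rose by 3.29 ± 0.47 (adjusted p = 9.92e-05) and BMF by 3.21 ± 0.60 (adjusted p = 0.000518). ATP6V1B1 (3.02), OLFML2A (2.82), GPNMB (2.78), BPIFB1 (2.73) and PLAAT4 (2.54) followed, with adjusted p from 0.00119 to 0.00763. ETV4 fell by 5.10 ± 1.01 (adjusted p = 0.000756), ETV5 by 4.52 ± 0.95 (adjusted p = 0.00113) and SPRY4 by 4.37 ± 0.75 (adjusted p = 0.000274). The phosphatase gene DUSP6 fell by 2.66 ± 0.56 (adjusted p = 0.00109). TERT fell by 2.85, the replication factor MCM10 by 2.81 and CDC25A by 2.67, with adjusted p = 0.00259, 0.00112 and 0.00079. MYEOV fell by 3.45 and VGF by 2.74 (adjusted p = 0.024 and 0.0269), and these calls were lost when some lines were left out. The MYEOV estimate was then -3.31 without A375, -2.70 without A549, -3.48 without PC9 and -2.93 without RT112. The VGF estimate was -1.5 without A375 and -2.92 without A549.

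All 25 proliferation genes tested fell across lines (25 adjusted over the list alone), with a median log2 change of -1.98. RRM2 fell by 2.48, AURKB by 2.28, MCM5 by 2.24 and E2F1 by 2.21, with AURKB higher in 1 line. The camera test gave adjusted p = 1.34e-13, and adjusted p = 0.324 with an estimated correlation. The line medians ran from -3.78 in A375 to 0.13 in H3122. Of 16 genes of homologous recombination and replication stress, 15 fell (15 adjusted over the list alone), including EXO1 (-2.24), BLM (-2.18), XRCC2 (-2.15) and BRCA2 (-2.07). Their median was -1.85 (adjusted p = 1.13e-08, and adjusted p = 0.302 with an estimated correlation). Of 16 MAPK output genes, 13 fell (14 adjusted over the list alone), with a median of -1.55 (adjusted p = 2.93e-07, and adjusted p = 0.299 with an estimated correlation). The lowest line median, in PC9, was -3.39, and -3.13 without the genes at 0.

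The FOXO targets KLHL24 (1.79, adjusted p = 0.000234), FBXO32 (1.43) and CCNG2 (1.11) rose with PIK3IP1. In total 8 of 11 FOXO targets rose (9 adjusted over the list alone), with a median of 0.93 (adjusted p = 0.000121, and adjusted p = 0.299 with an estimated correlation). FBXO32 lost its call without N87 (1.10), PC9 (1.24) or RT112 (1.28). The lysosome and autophagy genes GABARAPL1 (1.54), WIPI1 (1.27) and NEU1 (1.2) rose in 6 of 6 lines. Of the 18 genes of that list, 14 rose (15 adjusted over the list alone), with a median of 0.68 (adjusted p = 8.99e-06, and adjusted p = 0.299 with an estimated correlation). TP53INP1, a p53 target, rose by 2.40 ± 0.31 (adjusted p = 5.54e-05), and the pro-apoptotic BCL2L11 by 0.82 (adjusted p = 0.00747).

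Interferon response genes IFIT2 (1.80), IRF9 (1.62) and IFIT3 (1.53) rose in 6 of 6 lines. Of 15 such genes, 8 rose (9 up and 1 down adjusted over the list alone), with a median of 1.01 (adjusted p = 0.000681, and adjusted p = 0.399 with an estimated correlation). Antigen presentation genes HLA-F (1.87, adjusted p = 0.000881), HLA-DMA (1.67, adjusted p = 0.000184), HLA-E (1.17) and HLA-B (1.10) rose too. Of 13 in that list, 8 rose (9 adjusted over the list alone), with a median of 0.90 (adjusted p = 0.000121, and adjusted p = 0.367 with an estimated correlation). The receptor genes ERBB3 (1.17, adjusted p = 0.00256) and ERBB2 (0.88, adjusted p = 0.000488) rose in all 6 lines.

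Of the glycolysis genes LDHA fell by 1.28, ENO1 by 1.13 and PKM by 0.95, and 9 of 13 in the list were called down (9 adjusted over the list alone). The glycolysis median was -0.73 (adjusted p = 0.000188, and adjusted p = 0.324 with an estimated correlation). The amino acid synthesis genes PSAT1 (-2.49), PHGDH (-2.13) and ASNS (-2.03), counted in the integrated stress response list, fell. In that list 6 of 13 fell (6 adjusted over the list alone), with a median of -0.80 (adjusted p = 0.0247, and adjusted p = 0.6 with an estimated correlation). Its call was lost without RT112 (median -0.51). Of 15 cholesterol synthesis genes 5 fell (6 adjusted over the list alone), among them DHCR7 (-1.11) and STARD4 (-1.01), with a median of -0.50 (adjusted p = 0.0127, and adjusted p = 0.621 with an estimated correlation). That call was lost without PC9 (-0.33). Among 22 immediate-early and short-lived transcripts 7 rose and 1 fell (7 and 1 adjusted over the list alone), led by JUN (1.31), ID3 (1.16) and ZFP36 (1.10), with a median of 0.43 (adjusted p = 0.0247, and adjusted p = 0.399 with an estimated correlation). That call was lost without RT112 (0.34).

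The other lists tested across lines gave no camera call at 48 h. Ribosomal proteins had a median of -0.18 (2 of 26 down, 0 adjusted over the list alone, adjusted p = 0.054) and inflammatory cytokines 0.70 (3 up and 1 down of 9, adjusted p = 0.334). YAP and TEAD targets had 0.42 (4 up and 2 down of 18, adjusted p = 0.438), with NT5E down by -2.51 and CCDC80 up by 2.15. The drug-tolerant state genes had 0.21 (KDM5A up by 0.44, adjusted p = 0.386 for the list) and the transcription machinery -0.12 (1 up and 4 down of 16, adjusted p = 0.386). Mitochondrial genome transcripts had 0.06 (MT-CO1 up by 0.56, adjusted p = 0.614 for the list). For the remaining lists the signs differed. Receptor tyrosine kinases had a median of -0.10 and a mean of 0.01 (adjusted p = 0.597), p53 targets -0.06 and 0.10 (adjusted p = 0.614), and the BCL2 family -0.01 and 0.22 (adjusted p = 0.831). Mesenchymal genes had a median of 0.17, a mean of 0.02 and a test pointing down (adjusted p = 0.851).

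**Figure D1:**
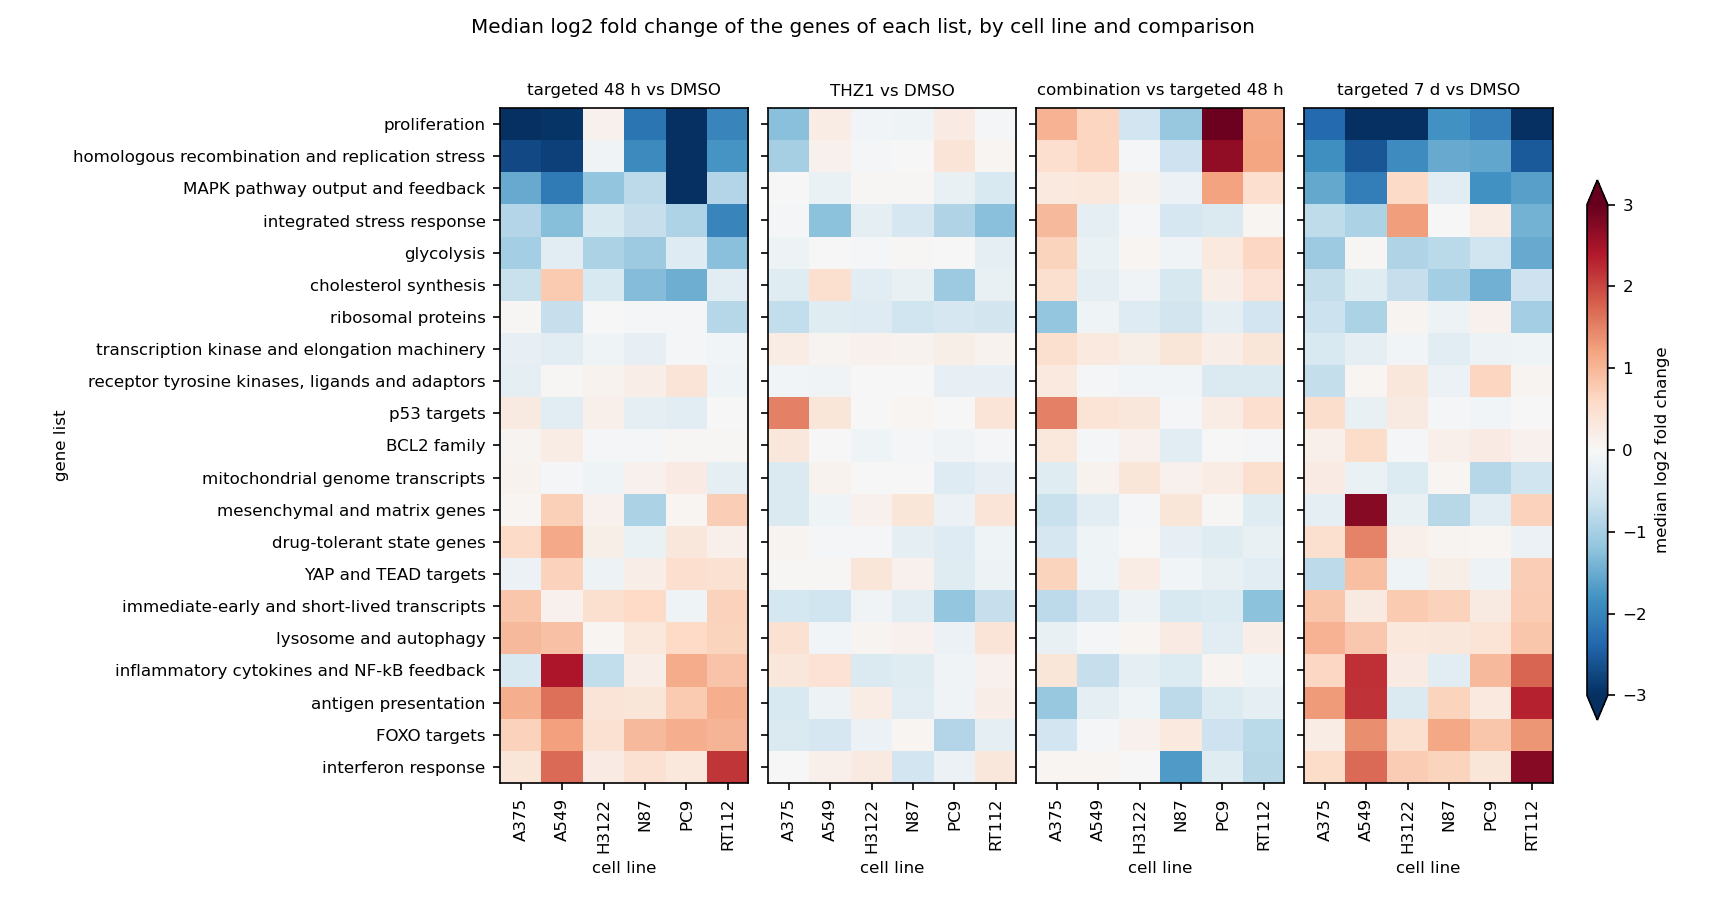
Median log2 fold change (colour) of the genes of each list (vertical axis) in each cell line (horizontal axis) for the 4 main comparisons. Proliferation genes had medians from -3.78 in A375 to 0.13 in H3122 under the targeted drug at 48 h.

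Among the largest changes within single lines were the following. In A375, ANGPTL7 went from 0.0585 to 241 ± 16.3 CPM (counts scaled to library size, mean ± SD of 3 libraries) and PCSK2 from 0.2 to 269 ± 5.14. CEMIP went from 383 ± 6.75 to 1.61 ± 0.514. In A549, UBD rose from 0.0584 to 99.7 ± 1.79 CPM and ETV4 went from 73.4 to 0.222. In H3122, RNASE1 rose from 6.62 to 92.5 ± 5.67 CPM and MMP1 went from 27.5 ± 1.53 to 0.395. In N87, PLA2G10 rose from 0.598 to 15.1 ± 0.372 CPM, and the hyaluronan synthase HAS2 went from 30.1 to 0.499. In PC9, TPPP3 rose from 2.72 to 59.5 CPM, and SPRY4 went from 33.3 ± 3.30 CPM to no counts in 3 libraries, which allows up to 0.091 CPM over the 3 (3 counts, counting error only). In RT112, CCDC85A rose from 0.136 to 26.5 CPM, VTCN1 from 0.963 to 61.9, and ETV5 went from 58.5 ± 6.25 to 0.148. Genes called per line numbered 10810 in A375, 10969 in A549, 6863 in H3122, 10887 in N87, 10406 in PC9 and 10564 in RT112.

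The second comparison asked what THZ1 did alone. Linker and core histone genes rose, the AP-1 gene JUND fell, and ribosomal protein transcripts, immediate-early transcripts and amino acid stress genes sat lower as groups. Of these group calls only the immediate-early one held (adjusted p = 0.0274 with an estimated correlation, against 0.101 and 0.107). POLR2A, the large subunit of RNA polymerase II, was higher in every line without passing the test across lines. Only 8 genes were called across lines, 6 up and 2 down, against 1352 at an unadjusted p of 0.05. DESeq2 called 194, a fit to the 2 arms alone 681, and leaving out A375, A549, N87 or RT112 left 0, PC9 2 and H3122 6.

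H1-2 rose by 2.23 ± 0.42 (SE of the fit to all arms, adjusted p = 0.0375). H2BC12 rose by 2.11 ± 0.37 (adjusted p = 0.028), and both rose in 6 of 6 lines. MBLAC1 rose by 0.90 and TTC14 by 0.81 (adjusted p = 0.0494 for each). JUND fell by 0.89 ± 0.15 (adjusted p = 0.0223) and OPLAH by 1.18 ± 0.22 (adjusted p = 0.0375). Reads of histone genes can be shared between near-identical copies. POLR2A had 0.84 ± 0.19 (adjusted p = 0.0813, higher in 6 lines), its regulator HEXIM1 0.59 (adjusted p = 0.256) and EGR1 -2.10 (adjusted p = 0.124, lower in 6 lines). RPS3 had -0.77 (adjusted p = 0.0894), RPS23 -0.71 (adjusted p = 0.0813) and ASNS -1.67 (adjusted p = 0.0966), each lower in 6 lines. CHAC1 had -1.62, INSIG1 -1.07, ALDH1A1 -1.2, CXCL8 -1.14, KLF9 -0.84 and SESN1 0.81, none called. FDXR (0.71), GDF15 (0.70) and MT-CO3 (-0.35) were not called either. With 1 line left out GDF15 ran from -0.16 to 1.12 and CXCL8 from -1.83 to -0.46. Without A375, A549, N87 or RT112 none of the genes named here for THZ1 was called. MBLAC1 and OPLAH lost their calls without any 1 of the 6 lines. H1-2 kept its call only without PC9, and H2BC12, JUND and TTC14 only without H3122.

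Immediate-early and short-lived transcripts had a median of -0.54, with 1 of 22 called down (10 adjusted over the list alone). Their camera result (adjusted p = 1.87e-09) was the only THZ1 list call to hold with an estimated correlation (adjusted p = 0.0274). Ribosomal proteins had a median of -0.52, and 0 of 26 were called over all genes against 25 adjusted over the list alone (adjusted p = 9.51e-28, and adjusted p = 0.101 with an estimated correlation). The integrated stress response had -0.82 (0 of 13 called, 4 adjusted over the list alone, adjusted p = 1.23e-07, and adjusted p = 0.107 with an estimated correlation). The transcription machinery had 0.08 with a mean of 0.18 (0 of 16, 5 adjusted over the list alone, adjusted p = 0.000681, and adjusted p = 0.101 with an estimated correlation). Cholesterol synthesis had -0.34 (0 of 15, 3 adjusted over the list alone, adjusted p = 0.000562, and adjusted p = 0.563 with an estimated correlation).

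The p53 targets had a median of 0.28 under THZ1 (0 of 16 called, 1 adjusted over the list alone, adjusted p = 0.000583, and adjusted p = 0.536 with an estimated correlation). That call was lost without A375 (0.10). FOXO targets had -0.37 (0 of 11, 0 adjusted over the list alone, adjusted p = 0.0374, and adjusted p = 0.563 with an estimated correlation), lost without PC9 (-0.23). Mitochondrial genome transcripts had -0.14 (0 of 11, 0 adjusted over the list alone, adjusted p = 0.0297, and adjusted p = 0.712 with an estimated correlation), lost without A375 (-0.10), PC9 (-0.11) or RT112 (-0.11). Proliferation genes had -0.18 (adjusted p = 0.34).

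In A375 all 16 p53 targets rose under THZ1, with a median of 1.5 that held with an estimated correlation (adjusted p = 0.000776), and GDF15 rose from 5.67 ± 0.424 to 324.5 ± 38.7 CPM. Its 25 proliferation genes all fell, with a median of -1.25 (adjusted p = 0.0212 with an estimated correlation). In A549 all 13 integrated stress response genes fell, with a median of -1.23 (adjusted p = 5.79e-07 with an estimated correlation). There CBS went from 87.9 ± 4.97 to 6.74 ± 1.41 CPM and ADM2 from 15.9 ± 2.8 to 0.753 ± 0.27. In PC9 all 16 cholesterol synthesis genes fell (median -1.08) and all 13 stress response genes fell (median -0.90), each with adjusted p = 0.000401 with an estimated correlation. In RT112, INHBB rose from 1.17 to 24.5 ± 2.55 CPM. In N87, H2BC4 rose from 1.60 to 14 ± 1.68 CPM, and in H3122 VGF rose from 2.33 to 24.9 ± 2.19 CPM. Genes called were 8918 in A375, 6909 in A549, 3439 in H3122, 4728 in N87, 8281 in PC9 and 6290 in RT112.

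**Figure D2:**
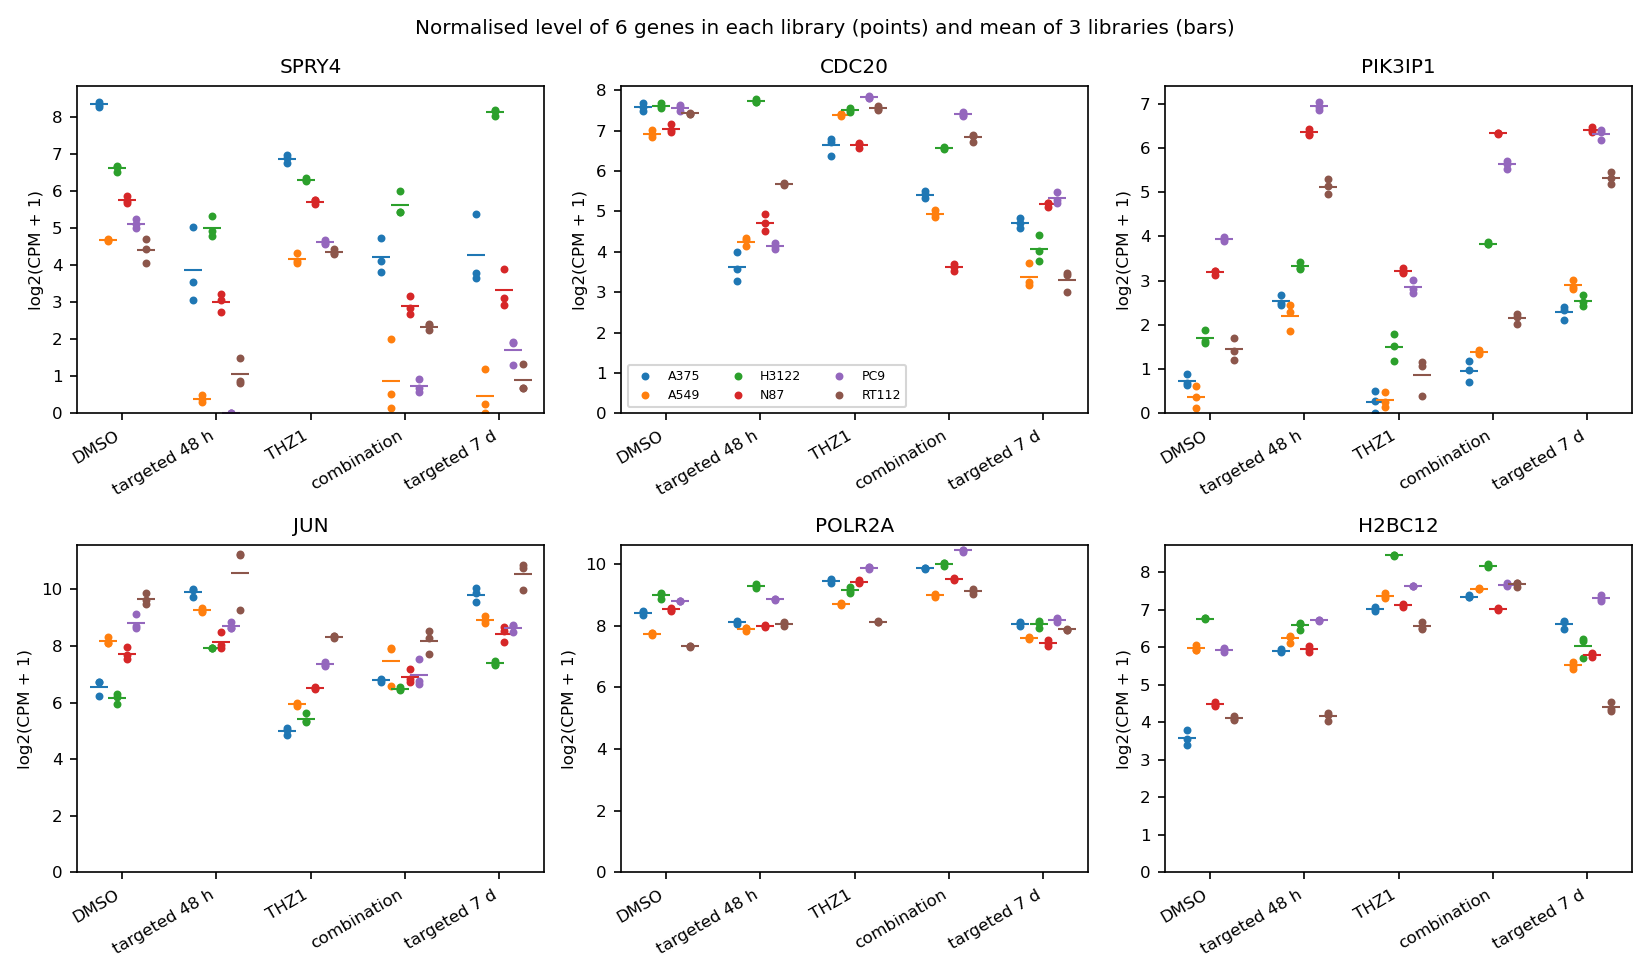
Level of 6 genes in each library (log2 of CPM plus 1, vertical axis) by arm (horizontal axis) and cell line (colour), with points for libraries and bars for means of 3. JUN is lower in the combination than under the targeted drug in 6 of 6 lines, by 2 on the log2 scale across lines.

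The third comparison, the combination against the targeted drug alone, asked what adding THZ1 changed. The immediate-early genes JUN, EGR1, FOS and ZFP36 fell, 13 of 26 ribosomal protein transcripts fell (adjusted p = 0.506 for the list with an estimated correlation), and POLR2A and HEXIM1 rose. Genes that the targeted drug had raised were lowered more often than matched genes on average over the lines, by little in N87. Proliferation genes went back up in 4 lines and were lower in the other two, N87 and H3122, of which H3122 had not lowered them under crizotinib alone (median 0.13). Across lines 0 of 25 were called in edgeR (adjusted p = 0.845 for the list with an estimated correlation), and in A375, 1 of the 4, the list gave adjusted p = 0.252 with an estimated correlation. Across lines 953 genes were called, 440 up and 513 down, with 805 in the same direction in all 6 lines. The count was 245 without A375, 211 without PC9, 236 without RT112, 1485 by DESeq2 and 184 with the 2 arms alone.

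POLR2A rose by 1.25 ± 0.19 (SE of the fit to all arms, adjusted p = 0.001, 6 of 6 lines). HEXIM1 rose by 1.05 ± 0.22 (adjusted p = 0.00665) and the CDK12 cyclin CCNK by 0.47 ± 0.11 (adjusted p = 0.0112). JUN fell by 2 ± 0.38 (adjusted p = 0.00298), ZFP36 by 1.03 (adjusted p = 0.00619), and EGR1 by 2.05 and FOS by 1.43 (adjusted p = 0.0314 and 0.0363). EBF4 fell by 2.43 ± 0.46 (adjusted p = 0.00328) and TLCD2 by 1.69 ± 0.31 (adjusted p = 0.00232). The non-coding ZNRD2-DT rose by 2.18 ± 0.36 (adjusted p = 0.00176) and the readthrough transcript RNASEK-C17orf49 by 1.98 ± 0.34 (adjusted p = 0.0018). RPS6 fell by 0.92 ± 0.17 (adjusted p = 0.00214), RPL13 by 0.91, RPL7A by 0.86 and RPS23 by 0.83. Calls that depended on single lines were those of EGR1 (-1.90 without A375, -2.24 without N87, -2.07 without PC9, -1.87 without RT112) and FOS (-1.17, -1.57, -1.53 and -1.35 without the same lines). HEXIM1 (0.99) and ZFP36 (-0.91) lost theirs without RT112, and CCNK without A375 (0.35) or PC9 (0.47).

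VGF (3.25, adjusted p = 0.0303) and the neuronal immediate-early gene ARC (2.94, adjusted p = 0.00774) rose in 6 of 6 lines. BPIFB1 (-2.60, adjusted p = 0.0337), AMY2B (-2.20, adjusted p = 0.012), UBA7 (-1.96, adjusted p = 0.0373) and HLA-F (-1.55, adjusted p = 0.0144) fell in 6 of 6. The p53 target FDXR (1.34, adjusted p = 0.0164) and CCND1 (0.97, adjusted p = 0.038) rose in 6 of 6 lines, as did BRAF (0.47, adjusted p = 0.0392). These calls were lost on leaving out lines. VGF lost its call without A549 (3.40), PC9 (3.30) or RT112 (2.87), ARC without A375 (2.49) or PC9 (2.89), and AMY2B without A375 (-1.95). HLA-F lost it without A375 (-1.31) or PC9 (-1.44), and UBA7 without A375 (-1.63), N87 (-1.80), PC9 (-2.02) or RT112 (-1.73). FDXR lost it without A375 (0.90), PC9 (1.45) or RT112 (1.34), and CCND1 without A375 (0.81), H3122 (0.96), PC9 (0.97) or RT112 (0.81). BPIFB1 lost it without any line but A549, and BRAF without any line. Not called were PIK3IP1 (-1.11, adjusted p = 0.112), IRF9 (-0.91, adjusted p = 0.077) and CCNE2 (1.13, adjusted p = 0.199).

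The transcription machinery list had a median of 0.31, with 3 of 16 up (10 adjusted over the list alone), and its camera call held (adjusted p = 8.57e-06, and adjusted p = 0.0423 with an estimated correlation). Ribosomal proteins had -0.53, with 13 of 26 down (18 adjusted over the list alone, adjusted p = 3.47e-14, and adjusted p = 0.506 with an estimated correlation). Immediate-early transcripts had -0.62, with 6 of 22 down (2 up and 12 down adjusted over the list alone, adjusted p = 8.57e-06, and adjusted p = 0.0979 with an estimated correlation). The p53 targets had 0.58, with 3 of 16 up (7 adjusted over the list alone, adjusted p = 0.000768, and adjusted p = 0.699 with an estimated correlation). Antigen presentation had -0.53, with 1 of 13 down (6 adjusted over the list alone, adjusted p = 0.00266, and adjusted p = 0.845 with an estimated correlation).

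Proliferation genes had a median of 0.58 in the combination against the targeted drug, with 0 of 25 called over all genes and 0 adjusted over the list alone (adjusted p = 0.00175, and adjusted p = 0.845 with an estimated correlation). That list call was lost without PC9 (0.17). In PC9 all 25 rose, with a median of 2.95 (adjusted p = 0.00101 with an estimated correlation). There CCNE2 went from 0.335 to 13.0 ± 0.892 CPM and ORC1 from 1.19 ± 0.158 to 40.5 ± 1.74. In RT112 all 25 rose (median 1.17) and in A549 22 of 25 rose (median 0.65), with adjusted p = 0.0145 and 0.00885 with an estimated correlation. In A375 20 rose and 2 fell (median 1.04, adjusted p = 4.46e-06, and adjusted p = 0.252 with an estimated correlation). In N87 23 fell (median -1.14) and in H3122 16 fell and 3 rose (median -0.58), with adjusted p = 0.00312 and 0.017 with an estimated correlation. Homologous recombination genes had 0.63 (0 of 16 called, 0 adjusted over the list alone, adjusted p = 0.00522, and adjusted p = 0.845 with an estimated correlation), lost without PC9 (0.28).

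**Figure D3:**
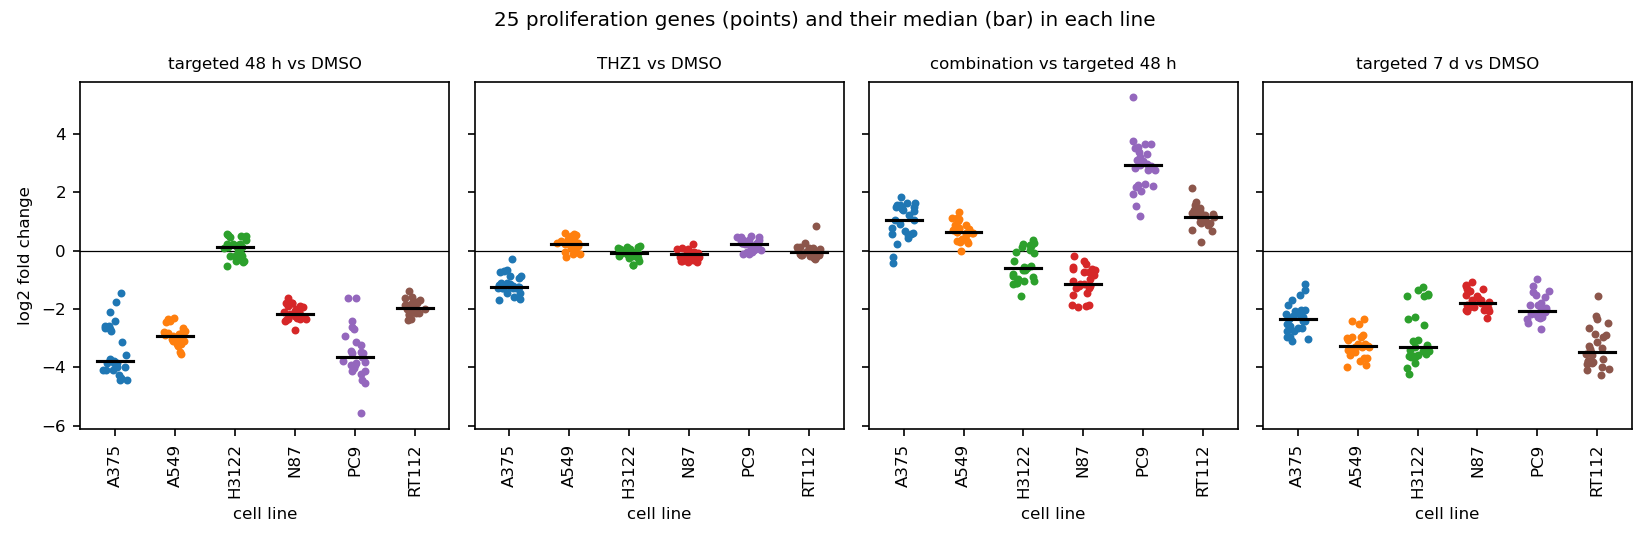
Log2 fold change (vertical axis) of the 25 proliferation genes (points) with their median (bar) in each cell line (horizontal axis) for the 4 main comparisons. In the combination against the targeted drug the median was 2.95 in PC9 and -1.14 in N87.

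Genes that the targeted drug raised at least 2-fold at 48 h were then followed into the combination. The percent called lower than under the targeted drug alone was 74.2 of 2255 genes in A375, 45.7 of 2601 in A549 and 28.0 of 778 in H3122. It was 27.1 of 2139 in N87, 74.9 of 1560 in PC9 and 64.3 of 1926 in RT112. Other genes matched on expression gave 22, 12.5, 8.20, 20.5, 24.9 and 22.7 percent in the same order. The mean difference was 33.9 points (SD 17.9 over 6 lines), above 0 in 6 of 6 lines (exact two-sided sign-flip test, p = 0.0312, the smallest 6 lines can give). With a 10 CPM minimum it was 37.1 points with an exact sign-flip p = 0.0625, as N87 then had -0.948. Simulated data without a link between the comparisons gave 34.6, 23.0, 17.0, 25.7, 34.0 and 33.6 percent. In these simulations raised genes exceeded matched genes by 6.23, 4.95, 5.16, 4.70, 6.04 and 6.89 points. The real differences were larger than the simulated ones by a mean of 28.2 points (SD 17.2), and by 1.88 points in N87. In N87 21.8 percent of raised genes were called higher in the combination.

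Named examples of such genes were ANGPTL7 in A375, from 241 ± 16.3 CPM under vemurafenib to 0.280 in the combination, and PPBP in A549, from 18.6 to 1.16. IFI44L in N87 went from 26.1 ± 3.53 to 0.441 ± 0.172 CPM. In N87 all 21 interferon response genes fell, with a median of -1.70 (adjusted p = 0.00154 with an estimated correlation). CP in H3122 went from 8.19 to 0.925 CPM, and COL21A1 in PC9 from 2.19 to 0.135 CPM. In RT112 IGFBP5 went from 28.3 ± 2.52 to 0.790 ± 0.412 CPM, while ETV4 rose from 1.10 to 39.7 ± 0.596 and ETV5 from 0.148 to 8.53 ± 0.836, against 150 and 58.5 in DMSO. In A375 the p53 targets rose in 16 of 16 (median 1.5, adjusted p = 0.0111 with an estimated correlation). Genes called were 11015 in A375, 6106 in A549, 4388 in H3122, 8567 in N87, 10481 in PC9 and 9775 in RT112.

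**Figure D4:**
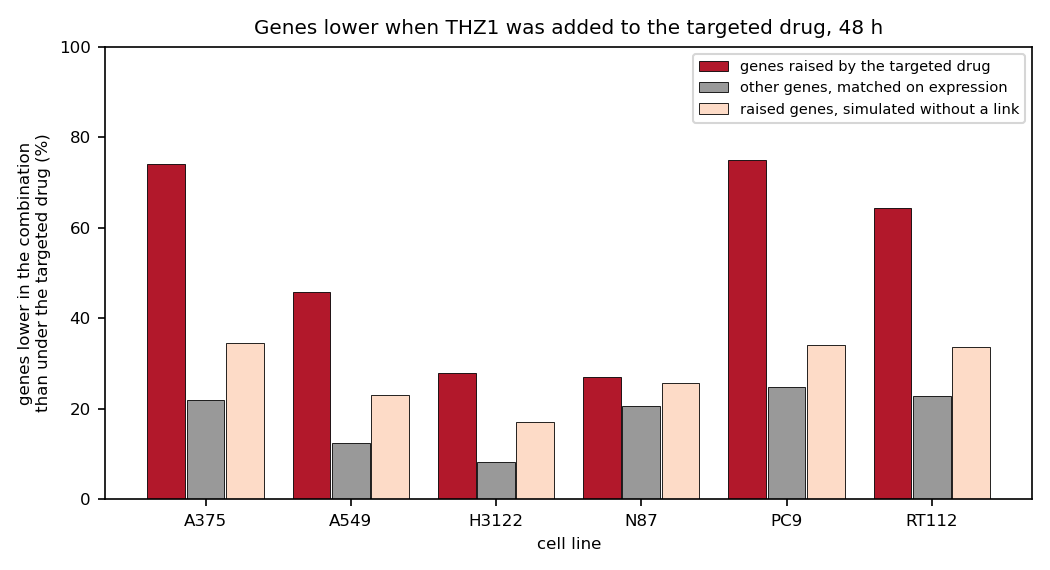
Percent of genes (vertical axis) called lower in the combination than under the targeted drug at 48 h in each cell line (horizontal axis), as bars for genes raised by the targeted drug, matched genes and simulated data. PC9 had 74.9 percent against 24.9 in matched genes, and N87 27.1 against 20.5.

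Against DMSO, the combination called 3651 genes across lines, 1832 up and 1819 down, and 1904 when N87 was left out. MAPK output genes had a median of -1.40, with 12 of 16 down (14 adjusted over the list alone, adjusted p = 2.87e-06, and adjusted p = 0.378 with an estimated correlation). Proliferation genes had -1.44, with 17 of 25 down (23 adjusted over the list alone, adjusted p = 5.43e-09, and adjusted p = 0.378 with an estimated correlation). Ribosomal proteins had -0.73, with 21 of 26 down (25 adjusted over the list alone, adjusted p = 1.36e-14, and adjusted p = 0.378 with an estimated correlation). The interaction, the effect of THZ1 under the targeted drug minus its effect in DMSO, called 0 genes in edgeR. At an unadjusted p of 0.05 there were 255, and DESeq2 and limma called 0 each, with 326 and 246 unadjusted. Each of these counts is under 0.05 of the 11877 genes tested, the share that a test without any effect gives. The tests were thus conservative here, and their 0 calls are no evidence that the drugs do not interact.

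The fourth comparison asked which genes differed after 7 days of the targeted drug. Mitotic and replication genes were lower than at the 48 h vehicle control in every line, including H3122. MAPK output was lower in 5 lines and was above vehicle in H3122. Antigen presentation, interferon, NF-kB feedback and lysosomal genes were higher as groups, and cholesterol synthesis and glycolysis genes lower. Camera called 12 of 21 lists, and 0 with an estimated correlation (adjusted p = 0.319 to 0.4 for the lists named here). Across lines 5122 genes were called, 2707 up and 2415 down, 3127 of them in the same direction in all 6 lines, and with the 2 arms alone 2894 were called.

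CCDC80 rose by 3.74 ± 0.66 (SE of the fit to all arms, adjusted p = 0.000195). AMY2B rose by 3.55 ± 0.54 (adjusted p = 6.22e-05) and BMF by 3.41 ± 0.61 (adjusted p = 0.000208). PIK3IP1 (3.29), SELENOP (3.14), the lysosomal protease CTSS (3.02), OLFML2A (2.95) and IQCN (2.88) rose in 6 of 6 lines. HMMR fell by 2.94 ± 0.54 (adjusted p = 0.000259), BUB1 by 2.81 ± 0.49 (adjusted p = 0.00018) and CDC20 by 2.81 ± 0.57 (adjusted p = 0.000539). CDC25A, POLE2 (-2.89), DLGAP5 (-2.88), MCM10 (-2.85), MND1 (-2.82), AURKB (-2.8) and PLK1 (-2.74) fell as well. ETV4 fell by 3.83 (adjusted p = 0.00313), ETV5 by 3.48, SPRY4 by 2.81 and DUSP6 by 2.12, each higher in 1 line. In H3122, SPRY4 went from 93.3 CPM in DMSO and 30.6 at 48 h to 260.6 at 7 days.

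All 25 proliferation genes fell (25 adjusted over the list alone), with a median of -2.45 (adjusted p = 1.47e-14, and adjusted p = 0.319 with an estimated correlation). Of the homologous recombination genes 14 of 16 fell (15 adjusted over the list alone), with EXO1 at -2.46 and a median of -2.01 (adjusted p = 1.26e-07, and adjusted p = 0.319 with an estimated correlation). Of the MAPK output genes 9 of 16 fell (9 adjusted over the list alone, median -0.99, adjusted p = 0.00233, and adjusted p = 0.4 with an estimated correlation). Ribosomal proteins had a median of -0.35, with 7 of 26 down (6 adjusted over the list alone, adjusted p = 0.00118, and adjusted p = 0.618 with an estimated correlation). RPS2 fell by 0.84 and RPL5 by 0.51.

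HLA-F rose by 2.28 ± 0.39 (adjusted p = 0.000138) and HLA-B by 1.82 ± 0.29 (adjusted p = 8.78e-05), in 6 of 6 lines. Of 13 antigen presentation genes 10 rose (10 adjusted over the list alone, median 1.21, adjusted p = 2.44e-05, and adjusted p = 0.327 with an estimated correlation). IFI6 rose by 2.59 ± 0.55 (adjusted p = 0.000827) and IRF9 by 1.95, and 10 of 15 interferon genes rose (11 adjusted over the list alone, median 1.32, adjusted p = 0.000292, and adjusted p = 0.36 with an estimated correlation). ICAM1 rose by 2.23 ± 0.40 (adjusted p = 0.000216), TNFAIP3 by 1.53 and RELB by 1.35. Of 9 inflammatory genes 5 rose (5 adjusted over the list alone, median 1.00, adjusted p = 0.0279, and adjusted p = 0.4 with an estimated correlation), and that call was lost without A549 (1.06) or RT112 (0.79). ATF3 rose by 1.91 ± 0.29 (adjusted p = 5.46e-05) and ZFP36 by 1.32, and 9 of 22 immediate-early genes rose and 1 fell (9 and 1 adjusted over the list alone, median 0.56, adjusted p = 0.00163, and adjusted p = 0.319 with an estimated correlation).

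GABARAPL1 (1.69), WIPI1 (1.36), NEU1 (1.24) and TPP1 (1.03) were among 14 of 18 lysosome genes that rose (15 adjusted over the list alone, median 0.73, adjusted p = 1.64e-05, and adjusted p = 0.319 with an estimated correlation). KLHL24 (1.41) and KLF9 (1.34) were among 8 of 11 FOXO targets that rose (8 adjusted over the list alone, median 0.99, adjusted p = 0.00132, and adjusted p = 0.319 with an estimated correlation). SQLE (-1.31), DHCR7 (-1.22) and STARD4 (-1.08) were among 9 of 15 cholesterol genes that fell (9 adjusted over the list alone, median -0.92, adjusted p = 0.000683, and adjusted p = 0.4 with an estimated correlation). LDHA (-1.32), ENO1 (-1.08) and GPI (-1) were among 8 of 13 glycolysis genes that fell (8 adjusted over the list alone, median -0.69, adjusted p = 0.000817, and adjusted p = 0.36 with an estimated correlation). TP53INP1 rose by 1.90, DDIT3 by 1.41 and ERBB2 by 0.96 ± 0.17 (adjusted p = 0.000154), and MNAT1, the assembly factor of the CDK7 complex, fell by 0.71 (adjusted p = 0.000126).

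In A375 the melanocyte gene DCT went from 0.230 to 510 ± 15.4 CPM at 7 days. In A549 the imprinted RNA H19 went from 3781 to 8.79 CPM, and 11 of 14 mesenchymal genes rose and 2 fell (median 2.74, adjusted p = 0.00448 with an estimated correlation). Across lines that list had a median of 0.08 at 7 days (adjusted p = 0.94), and its median was below 0 in 4 of 6 lines. In H3122, PAEP went from 12.7 to 1451 ± 55.2 CPM and ALDH3A1 from 63.8 to 1.23. In N87, UPK1A went from 0.295 to 35.9 ± 1.30 CPM and PSCA from 8.18 to 279.9 ± 39.6. In PC9, SERPINB2 went from 1.10 to 104.6 ± 5.89 CPM and the desaturase SCD from 1236 ± 49.7 to 62.4 ± 2.45. In RT112, CRISP3 went from 1.94 to 302.6 CPM and ANXA10 from 34.5 to 0.129. RT112 interferon genes had a median of 2.73, with 19 of 20 up (adjusted p = 0.000271 with an estimated correlation). Genes called were 11387 in A375, 11023 in A549, 9994 in H3122, 10876 in N87, 10773 in PC9 and 11283 in RT112.

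Between 7 days and 48 h of the targeted drug, edgeR called 0 genes across lines. At an unadjusted p of 0.05 there were 757, DESeq2 called 26 (881 unadjusted) and limma 0 (721 unadjusted). As groups, MAPK output genes had a median of 0.62 (adjusted p = 1.3e-06, and adjusted p = 0.367 with an estimated correlation) and integrated stress response genes 0.82 (adjusted p = 8.4e-08, and adjusted p = 0.36 with an estimated correlation), with 0 members called in either.

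Among the genes of the drug targets, ERBB2 rose at 48 h and 7 days, and CDK12 fell at both times (-0.31 and -0.45, adjusted p = 0.0348 and 0.00321). The 48 h CDK12 call was lost without A375 (-0.24), A549 (-0.27), H3122 (-0.33) or N87 (-0.28). CDK7 had -0.12 at 48 h, 0.03 under THZ1 and 0.39 in the combination against the targeted drug, none called (adjusted p = 0.571, 0.981 and 0.108). EGFR, MAP2K1 and MAP2K2 were not called in any of the 4 comparisons across lines, and ALK was not tested across lines.

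Changes correlated above 0 in all 15 pairs of lines in each of the 4 comparisons. Over 12036 genes, the median correlation of log2 changes between pairs of lines was 0.519 at 48 h (0.214 to 0.648 over 15 pairs), 0.274 for THZ1 (0.176 to 0.357), 0.228 for the combination against the targeted drug (0.11 to 0.563) and 0.435 at 7 days (0.312 to 0.607). In the combination against the targeted drug N87 and PC9 shared 1515 genes called up and 1775 called down, and 2164 were called in opposite directions. These correlations are across genes, which are not independent replicates. Called in the same direction in all 6 lines were 450 genes up and 991 down at 48 h, against 10.9 and 28.3 if lines were independent. For THZ1 there were 107 up and 205 down, against 1.10 for each, for the combination against the targeted drug 195 and 209, against 7 and 3.5, and at 7 days 477 up and 1477 down, against 16.6 and 52.6. The independent values multiply the call shares of the 6 lines, as if every gene were equally easy to call. They are too low if some genes are easier to call in every line, so the excess can be overstated.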

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

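The tests of untreated cells, of exchanged libraries and groups, and of THZ1 alone against simulated data, and the counts over other splits of the samples, were chosen only after the results were seen.

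Genes raised by the targeted drug were lowered in the combination more often than matched genes, by a mean of 33.9 points. Both comparisons use the same targeted-drug libraries, but genes chosen by the 7-day comparison, which shares none with them, still gave 26.0 points (SD 15.9, above 0 in 6 of 6 lines, lowest 1.28 in H3122). A lowering by THZ1 of the same genes in vehicle stays open for the mean over lines. Under THZ1 alone the difference was 0.598 points (SD 9.94, exact two-sided sign-flip p = 0.906). Less that of data simulated without a link, as both comparisons use the DMSO libraries, it was 5.69 points (SD 9.82, exact two-sided sign-flip p = 0.156). This excess was above 0 in 5 of 6 lines, with 23.9 in PC9, 1.3 in A375 and -5.05 in RT112. In A375 and RT112 the raised genes had median log2 changes of 0.132 and 0.336 under THZ1 alone. Against the targeted drug their medians in the combination were -1.14 and -0.74, which argues against this explanation in those lines. A general return toward the vehicle state is consistent with the genes that the targeted drug lowered, which were higher in the combination by a mean of 28.2 points (SD 26.1, 5 of 6 lines, -16.8 in N87, exact two-sided sign-flip p = 0.0938). Genes lowered at 7 days gave 20.2 points (SD 23.3, above 0 in 4 of 6 lines, exact two-sided sign-flip p = 0.125), with -13.4 in N87 and -4.42 in H3122, so a weaker response in both directions is a candidate explanation for 4 lines and stays open.

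Proliferation genes rose in the combination against the targeted drug in 4 lines and fell in the other two. PC9 (median 2.95) and N87 (-1.14), picked as the highest and lowest of the 6 lines and therefore given without a p, differed by 4.02 at the median. Untreated cells would bring every transcript at their share of its DMSO level, and are argued against in PC9 and RT112, where 58 and 66 abundant genes lay under 0.5 of that level in all 3 combination libraries at the shares of 62.8 and 42.4 percent that the proliferation genes need. In A375 and A549 the shares needed were 9.61 and 10.1 percent, only 4 and 9 genes lay that low, and untreated cells stay open. Exchange of single libraries is argued against, since 18 of 18 combination libraries correlated best with another of their own group, and exchange of whole groups because in 6 of 6 lines all 3 carried the changes that both drugs made in the other lines and were nearest to their own line, while the roles of line, drug and THZ1 dose are confounded.

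Ribosomal protein transcripts sat lower under THZ1 in all 6 lines, with line medians from -0.74 to -0.36. Other genes matched on length and abundance had medians no lower than -0.0894. Length was that of the longest annotated transcript of a gene. Its median was 1780 nucleotides for the ribosomal proteins and 1880 to 2260 for the matched genes, by line. The longest transcript may not be the one expressed, so the match cannot decide on a loss of short abundant transcripts, which stays open. The median across lines was -0.453 with library size alone and -0.52 with TMM. Exchanging these scalings moved the median of all genes by only 0.064, so the choice between them is argued against as the cause. Other forms of scaling were not tested by it, as the exchange could not have removed the fall. Translation factors whose transcripts carry the same 5' terminal oligopyrimidine tract had a median over lines of -0.445, below 0 in 6 of 6 lines. A shared control of such transcripts is therefore a candidate explanation, found and tested on the same data.

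The following values lie far from those of the other lines by Dixon's criterion, which 15 of 185 tested groups passed and which chance passes in about 1 in 20 groups. Under THZ1, A375 had a proliferation median of -1.25 (others -0.12 to 0.24) and a homologous recombination median of -1 (others -0.05 to 0.38). There its p53 target median was 1.5 (others -0.01 to 0.39) and its BCL2 family median 0.33 (others -0.12 to 0.02). Its p53 median in the combination against the targeted drug was also 1.5 (others -0.04 to 0.51). In that comparison A375 had 1.07 for CDK7 (others 0.17 to 0.47), 1.28 for EGFR (others -0.49 to 0.14) and -5.40 for EBF4 (others -2.55 to -1.22). H3122 had -0.80 for AMY2B (others -2.99 to -2.28), and PC9 -0.73 for MAP2K2 (others -0.05 to 0.16). A549 had 0.45 for CDK12 under THZ1 (others 0.15 to 0.26), 0.28 for IQCN at 7 days (others 2.89 to 3.38) and 6.04 for PLAAT4 at 48 h (others 1.42 to 2.84). A375 had -5.83 for VGF at 48 h (others -2.03 to -1.25). H3122 had 6863 genes called at 48 h (others 10406 to 10969).

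The integrated stress response at 7 days had a median of 1.26 in H3122 and -0.94 in A549, the 2 lines whose list calls held with an estimated correlation. They differed by 2.70 at the median, given without a p as the pair was picked for its opposite calls. RT112 had the lowest line median, -1.41 (adjusted p = 0.377 with an estimated correlation).

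For the counts across lines against DMSO and between combination and targeted drug, only 1 of 32 splits, the real one, gave as many genes. That is the smallest share that 32 splits can give, and it argues against chance for fits to the 2 arms alone. The reported counts from all arms, 8 for THZ1 and 953 for the combination against the targeted drug, were not split. With the 2 arms alone the real split called 3462 genes at 48 h, 681 for THZ1, 184 for the combination against the targeted drug, 2894 at 7 days and 2068 for the combination against DMSO. The highest other split called 1, 1, 0, 0 and 0. For 7 days against 48 h, all 32 splits called 0 genes, the real one included, so chance is not excluded. Within lines 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each of the 24 comparisons only 1 split, the real one, called any gene, between 5047 and 10936, and the highest other called 0.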

How the results depend on the processing

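The setting without the libraries that stood apart was chosen after seeing the data. Of 445 gene counts under alternatives, 399 stayed within 1.5 times the reported count and 46 did not. Of 924 list tests 848 kept their direction and side of the threshold, 57 lost and 19 gained a call. Of 4192 tests of named genes across lines 3651 did so, 505 lost and 35 gained a call, and in single lines 4734 of 4921 did so, 134 lost and 50 gained one. A change of sign between values without a call counts as unchanged. Where the cause is not named below, the cause was not tested.

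Without a term for the line, 88 genes were called at 48 h, 0 for THZ1, 0 for the combination against the targeted drug, 519 at 7 days and 34 for the combination against DMSO, since differences between lines then count as spread. With only the arms compared, the spread is estimated from those arms alone. The THZ1 count then rose from 8 to 681. Counts fell from 953 to 184 for the combination against the targeted drug, from 5122 to 2894 at 7 days and from 3651 to 2068 for the combination against DMSO. Why the THZ1 count moved the other way was not tested. DESeq2 called 194 for THZ1, 1485 for the combination against the targeted drug and 26 for 7 days against 48 h. Library size alone gave 13 for THZ1. Leaving out 1 line gave 3230 to 4470 genes at 48 h, 0 to 6 for THZ1, 211 to 1151 for the combination against the targeted drug, 3952 to 4784 at 7 days and 1904 (without N87) to 3625 for the combination against DMSO. Without A375, PC9 or RT112 the third count was 245, 211 or 236. Without the 5 libraries that stood apart the counts were 4349, 6, 910, 5057 and 3616.

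Within lines, filters, scalings, tests, the replicate block and leaving out single libraries kept counts within 1.5 times. The replicate block gave 6838 genes at 48 h and 3281 for THZ1 in H3122. A 2-fold minimum, which can only remove genes, gave at 48 h 4285 in A375, 4511 in A549, 1245 in H3122, 3572 in N87, 3142 in PC9 and 3580 in RT112. For THZ1 it gave 2200, 837, 370, 404, 1001 and 852 in the same order. For the combination against the targeted drug it gave 4005, 681, 533, 1544, 2808 and 2409, and at 7 days 4621, 5068, 3188, 3401, 3032 and 4683.

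The percent of raised genes lower in the combination was higher in all 6 lines with the 10 CPM minimum, which tests fewer genes. It was then 87.7 in A375, 60.9 in A549, 41.9 in H3122, 34.1 in N87, 89.7 in PC9 and 77.2 in RT112. With a 2-fold fall required, which can only remove genes, it was lower in all 6, at 54.4, 12, 14.8, 12.5, 42.0 and 37.2. With genes chosen at 7 days it was 65.4 in A375, 12.5 in H3122, 31.7 in N87 and 58.9 in PC9. Library size alone gave 69.1 in A375, and DESeq2 39.9 in A549. Leaving out 1 library gave 40.6 (without combination replicate 1) to 46.2 in A549. These shares count as moved beyond the jackknife SD over 9 fits. The mean difference over lines was 37.1 with the 10 CPM minimum (exact sign-flip p = 0.0625, N87 -0.948) and 30.2 to 39.4 without 1 line. With 5 lines the smallest possible p is 0.0625.

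Of 84 list tests across lines 38 were called, 35 to 40 without 1 line and 2 with an estimated correlation. Under fry, which asks only whether a list's genes move one way on balance, 74 of the 84 were unchanged, 8 lost and 2 gained a call. It called 11 lists at 48 h, 4 for THZ1, 3 for the combination against the targeted drug and 14 at 7 days. Camera called 11, 8, 7 and 12. DUSP6 at 7 days had 0.26 without a line term. With library size alone PC9 MAP2K1 had -0.10 at 48 h, and RT112 CDK12 and EGFR had 0.05 each at 7 days. That scaling moved the median of all genes by over 0.1 in A375 for THZ1 (0.116) and the combination against the targeted drug (0.164), in PC9 at 48 h (-0.132), and in RT112 at 48 h (0.161) and 7 days (0.149). It raised the percent of calls that were rises from 46.2 to 62.7 for the combination against the targeted drug across lines. The shallowest library, of 5.64 M counts, limits genes near 1 CPM.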

Other observations

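The nuclear-encoded respiratory chain list, the histone list and its test, and the comparison of H3122 with the other lines were chosen only after results were seen.

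Lineage markers were tested in lines with at least 5 tested genes of a list. In A375, 4 of 7 melanocyte markers rose at 48 h (median 0.63, mean 2.34, adjusted p = 6.03e-08, and adjusted p = 0.0107 with an estimated correlation) and 7 of 7 at 7 days (median 1.85, adjusted p = 0.0127 with an estimated correlation). In the combination 4 of 7 fell against vemurafenib alone (median -1.11, adjusted p = 0.0074 with an estimated correlation). In H3122, 4 of 6 lung epithelial markers rose at 48 h (median 0.80, adjusted p = 6.41e-05, and adjusted p = 0.0117 with an estimated correlation), and NKX2-1 had a mean of 245 CPM in DMSO and 710 under crizotinib. Its gastric markers had a median of -0.18 and a mean of -1.33 (1 up and 2 down of 5, adjusted p = 6.41e-05, and adjusted p = 0.0521 with an estimated correlation). Its fibroblast and endothelial markers had 1.5 (3 up and 1 down of 6, adjusted p = 0.00571, and adjusted p = 0.131 with an estimated correlation). In RT112, 5 of 10 urothelial markers rose and 3 fell at 48 h (median 0.56, adjusted p = 0.00036, and adjusted p = 0.103 with an estimated correlation). In N87 the same markers fell in 9 of 11 and rose in 1 when THZ1 was added (median -0.97, adjusted p = 0.00943 with an estimated correlation). Blood cell markers had fewer than 5 tested genes in every line, with PTPRC at most 1.10 CPM and MS4A1 at most 0.0328. Others were expressed, as CD68 ran from 2.06 to 118 CPM, and LYZ in RT112 had 2.79 in DMSO and 66.9 at 7 days. CD79A in N87 had 1.48 in DMSO, 10 under lapatinib and 15.5 in the combination, and HBA1 in RT112 had 0.529 in DMSO, 5.43 under BGJ398 and 6.19 in the combination. Lung markers in A549 were not called at 48 h (4 of 5 up, adjusted p = 0.107), and fewer than 5 lung markers in PC9 and gastric markers in N87 were tested.

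H3122 was set against the mean of the other 5 lines in an edgeR fit of all 90 libraries in 30 groups. Genes were counted at an adjusted p under 0.05. The spread in this fit is that between libraries, which may be technical replicates, and not between lines. H3122 was picked from the 6 lines after its values were seen, so the counts are no independent support. Its proliferation genes were higher at 48 h in 25 of 25 by a median of 2.98. At 7 days 6 of 25 were higher and 16 lower (median -0.60). Its MAPK output genes at 7 days were higher in 12 of 16 and lower in 0 (median difference 1.53), and at 48 h in 9 of 16 and lower in 1 (median difference 0.62). Nuclear-encoded respiratory chain genes, listed after the data were seen, had a median of -0.36 at 7 days, with 18 of 26 down across lines (camera p = 1.05e-07, and p = 0.126 with an estimated correlation).

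Histone genes were higher under THZ1 across lines, with a median of 1.61 over 12 genes of which 2 were called (camera p = 9.9e-22, and p = 0.0019 with an estimated correlation). As the list was chosen and tested on the same data, its p-values are no independent support. The line medians were 3.30 in A375, 0.57 in A549, 1.10 in H3122, 1.42 in N87, 1.03 in PC9 and 1.44 in RT112. One hypothesis was that more cells were in S phase. It is argued against in A375 alone, where all 8 S-phase genes fell (median -1.02). Their medians were -0.14 in H3122, -0.12 in N87, -0.10 in RT112 and 0.07 in A549, too small to decide. In PC9 the median was 0.41, with 5 genes up and 0 down, so the hypothesis stays open outside A375. No other cause was tested and reads of histone copies are shared. Across lines the list was also higher under the targeted drug alone, at 48 h with a median of 1.22 (6 of 12 up, camera p = 0.000978, and p = 0.233 with an estimated correlation) and at 7 days with 1.81 (9 of 12 up, p = 5.35e-05, and p = 0.151 with an estimated correlation). This rise was not shared by all lines. Line medians at 48 h were 1.57 in A375, -0.72 in A549, 0.47 in H3122, 1.65 in N87, 1.43 in PC9 and 0.12 in RT112. At 7 days they were 2.94, -1.08, -0.18, 1.39, 3.25 and 1.28 in the same order. In the combination against DMSO all 12 rose, with a median of 2.56 (p = 0.0115 with an estimated correlation), and against the targeted drug 6 rose, with a median of 1.43 (p = 0.0412 with an estimated correlation).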
